A study of Folsomia candida with 7 samples.

How the data were processed

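Two-colour Agilent arrays of whole-animal pools of Folsomia candida were analysed. Per the labels' protocols, RNA was extracted from all animals of a jar, about 30, with a spin-column kit, and 500 ng went into linear amplification and labelling with Cy3 or Cy5. Nothing in the labels says whether jars were prepared on separate occasions, so p-values measure the spread between these pools. Each pool was on a single array, so this spread includes that of labelling and hybridisation. Group, replicate number and dye of each sample came from the labels. Array names give the Cy3 and then the Cy5 sample, with C for control and AC for acetone control. Each of the 7 arrays compared samples of different groups, in a loop, and any further samples of the design were not analysed here. Every pair of groups met directly on a single array, except EC10 and EC50, so leaving out an array can remove the only direct comparison.

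Per the file headers, the scanner output was made with Agilent Feature Extraction 9.5.1.1 and holds, for every spot and channel, mean signal and local background as intensity on a linear scale, with flags for spots well above background, saturated spots and outliers. The deposited value table of the series holds log2 values of Cy5 over Cy3. Its scale, centring and direction are not stated and were found by comparison: each column correlated with the ratio of the same array's scanner values at 0.962 or more over spots well above background, with the same sign, with slopes between 0.779 and 0.872. Against the loess ratios used here the correlation was 0.996 or more, with slopes between 1.05 and 1.07, and column medians lay between 0.0044 and 0.016. Which background correction the authors used is not given in the sources used here. The submitters' processing notes name limma, with no version. The table was used as an alternative only.

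Spots were background corrected with normexp (offset 50) on the mean signal and median local background, and the log2 ratios were loess normalized within arrays, with control and outlier-flagged spots at weight 0, in limma 3.58.1 (R 4.3.3, statmod 1.5.0). The 536 control spots and outlier-flagged spots were left out, and the 3 spots of each of 5069 probes were averaged. Each probe stands for 1 transcript. Transcripts well above background in at least 3 of the 14 channels were kept. This left out 510, and 17 more lacked a ratio on at least 1 array, so that 4542 were tested. Levels are the log2 intensities of separate channels after loess and Aquantile normalization, given as mean ± SD over RNA samples. Replicates of a group correlated at 0.956 to 0.993, and no pair had identical values.

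The fit was limma's lmFit with 3 group coefficients and a dye intercept per transcript, followed by eBayes with an intensity trend. It left 3 residual degrees of freedom, to which the prior added 3.29. All adjusted p-values are Benjamini-Hochberg values over the transcripts tested, or over the gene lists for camera, and an adjusted p under 0.05 was called. A moderated F test covered the 4 groups. The fit was tested on simulated data with known changes, 50 transcripts of each size per run. The noise had the spread after eBayes, which differs less between transcripts than the raw residual spread. In 20 simulated runs on 4542 transcripts for EC50 against acetone control, an average of 142.3 were called, of which 7.6 were false. A list of 20 transcripts shifted by 0.5 reached a camera p under 0.05 in 100% of the runs. These transcripts were independent and all shifted alike, and the p was unadjusted, with camera's preset correlation of 0.01. The share does not carry over to lists of correlated transcripts or to adjusted p-values.

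Annotation came from the arrays' own column of best sequence matches to proteins of other species, which is old and often cut short. The reference table of the ASM221717v1 assembly uses other identifiers and was not matched to it. Of 5069 transcripts 2321 had a match, and 1077 of them an informative one. Fixed before the data were examined were 23 gene lists, found by keywords in the matches: cytochrome P450, glutathione S-transferase, other conjugating and detoxifying enzymes, ABC transporters, glutathione and cysteine supply, antioxidant defence, heat shock proteins and chaperones, proteasome and ubiquitin, ribosomal proteins, mitochondrial respiration, lipid metabolism, yolk and oogenesis, digestive proteases, carbohydrate hydrolases, cuticle and moulting, tubulin, muscle, neuronal, immune and haemocyte, beta-lactam biosynthesis, cell cycle, replication and histones, apoptosis and autophagy, and matches in endosymbionts, bacteria and yeast. Hyphens in the keywords were made optional because the arrays' text has none. For glutathione and cysteine supply and for apoptosis and autophagy the keywords found 0 transcripts. Missing or cut matches can hide members of any list. Tubulin and yolk had fewer than 5 found. This left 19 lists for camera, run with a preset correlation of 0.01 and again with an estimated one. With an estimated correlation camera is limited to the residual degrees of freedom of the fit, 3 here. A list can then hardly pass, so a failure there decides little where the estimate lies near the preset. Where the estimate is higher, as for ribosomal proteins (0.51) and glutathione S-transferases (0.23), the correlation itself also raises the p-value.

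The rule for named transcripts was: for both exposures against acetone control, the 8 largest called rises and falls with an informative match, up to 4 called members of each list, and for a list without a called member its member with the smallest p; for other comparisons the 3 largest called rises and falls; and, where fewer than 5 transcripts were called, the 5 informative ones with the smallest p, as values only. A match naming only a hypothetical, unknown or predicted protein was not informative, and after the annotation had been read, matches that give only a gene-model or clone number were also left out of the informative ones. A probe not well above background in any sample of a group has a bound only.

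The 7 arrays lay on 2 slides, 6 on the first and AC-3/EC50-1 alone on the second, so a slide block gives the same folds as leaving out that array, and the second slide alone gives no test. Alternatives covered the dye term, background correction, the scanner software's processed signals, scaling between arrays, both filters on dim transcripts, separate channels with and without the replicate number as a block, array weights, the deposited table, the slide and each array left out in turn.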

Results

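Gene expression was measured in the springtail Folsomia candida, a soil-living hexapod that reproduces without males, after 2 days in LUFA 2.2 soil, a standard natural test soil. Animals of the Berlin strain, 25 days old, were kept in untreated soil (control), in soil treated with the solvent only (acetone control), or in soil spiked with 2-phenylethyl isothiocyanate, the electrophilic compound released from the glucosinolate gluconasturtiin of cruciferous plants. The spiked concentrations were named EC10 (6.21 nmol/g dry weight) and EC50 (10.7 nmol/g dry weight). Each RNA sample was a pool of about 30 animals from 1 jar. The 7 arrays held 14 such samples, 3 of control, 3 of acetone control, 4 of EC10 and 4 of EC50, with a pair of samples hybridised directly to each array in Cy3 and Cy5. The share of probes well above background ran from 78.0% in control 4 to 98.1% in acetone control 4. Median raw Cy3 signals lay between 199.6 and 949.9 intensity units over the arrays and median Cy5 signals between 677.5 and 2526. Of 5069 transcripts on the array, 4542 were tested. The number of arrays limits the precision. Transcripts carry the identifier of the array and, in words, the protein of another species that their sequence matched best. No match was listed for 2748 of them, and genome positions are not given in the sources used here. Log2 folds are from within-array ratios and need not equal the difference of 2 mean levels, since the levels also carry differences between arrays.

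The first comparison asked what the low concentration changed relative to its solvent control. The 5 transcripts with the smallest p-values among those with an informative match are given first, and none passed the test. The match to maltase-glucoamylase, an enzyme that releases glucose from starch fragments (Fcc00529), was at 12.17 ± 0.50 log2 intensity (SD, n = 4) in EC10 and 11.82 ± 0.36 (SD, n = 3) in the acetone control, with a log2 fold of 0.97 (SE 0.22). Fcc00881, a match to the frog protein listed as Chiaprov, had a log2 fold of 0.97 (SE 0.24), although its mean levels were 10.51 ± 0.32 (SD, n = 4) and 10.39 ± 0.51 (SD, n = 3). The match to purine nucleoside phosphorylase, which splits nucleosides into base and sugar (Fcc04684), had a log2 fold of 0.71 (SE 0.20). A serine proteinase match (Fcc04942) had a log2 fold of -1.13 (SE 0.35), with 8.59 ± 0.38 (SD, n = 4) in EC10 and 9.12 ± 0.33 (SD, n = 3) in the acetone control. Fcc00585, whose match begins with the words ataxia telangiectasia, had a log2 fold of -0.43 (SE 0.11) and was well above background in 3 of 4 EC10 and 2 of 3 acetone control samples.

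In EC10 against acetone control, limma called 0 of 4542 transcripts (lowest adjusted p = 1.00). At an unadjusted p under 0.05 there were 139, 98 of them with a positive and 41 with a negative fold, where 227.1 would arise by chance on average. Correlation between transcripts can widen the spread around that average. The separate-channel fit also called 0, with 146 at that unadjusted level, and with the slide as a block 0 were called and 57 reached it. That number was 459 without array C-2/EC10-1, 55 without AC-3/EC50-1 and 76 without EC10-3/EC50-2. With scaling between arrays it was 359 and with array weights 742, both above the number by chance, with 0 called. The 95% confidence interval of a fold reached a median of 0.50 log2 units to either side.

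Among enzymes that modify foreign compounds, 0 of the 14 cytochrome P450, 17 glutathione S-transferase and 9 other conjugating and detoxifying transcripts passed the test in EC10 against acetone control. Of the P450 transcripts 9 had positive and 5 negative folds. All but Fcc05374 match oxidising haem enzymes, and Fcc05374 matches the reductase that passes electrons to them. A match to the mosquito enzyme CYP6N4v1 (Fcc01651) had a log2 fold of 0.37 (SE 0.12) and was well above background in 4 of 4 EC10 samples and 1 of 3 acetone control samples. Of the glutathione S-transferases, which conjugate electrophiles to glutathione, 13 had positive folds, with 0.23 (SE 0.10) for Fcc00851. Of the 9 other enzymes 8 had positive folds, with 0.32 (SE 0.17) for a carbonyl reductase match (Fcc01157). The camera test gave an adjusted p = 0.13 for both of these lists, and adjusted p = 0.82 with an estimated correlation. Of 7 ABC transporters, 3 had positive folds, and camera gave the direction as up while the median was below 0. The one with the smallest p, a bacterial substrate-binding protein match (Fcc05098), had a log2 fold of 0.60 (SE 0.30), but a level of 11.51 in EC10 replicate 1 against 9.85 to 9.93 in the other 3 replicates, and its mean level differed from the acetone control by -0.07.

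Stress and protein-turnover lists held folds of both signs at EC10. In the antioxidant list 9 of 12 folds were positive and 0 transcripts passed, in a range from -0.90 to 0.64, with 0.64 (SE 0.32) for a thioredoxin match (Fcc04514), a small disulfide-reducing protein. The heat shock and chaperone list had 4 positive and 6 negative folds, with 0.43 (SE 0.23) for a small heat shock protein match (Fcc01918). In the proteasome and ubiquitin list 8 of 19 folds were positive, with -0.13 (SE 0.07) for a ubiquitin ligase match (Fcc02779). Of 36 ribosomal protein transcripts 31 had positive folds, with a median of 0.12 and 0.41 (SE 0.20) for ribosomal protein L38 (Fcc01536). The list also holds a match to a ribosomal protein S6 kinase (Fcc04024), an enzyme rather than a part of the ribosome. The camera adjusted p of that list was 0.13, and adjusted p = 0.82 with an estimated correlation. Of 15 respiratory chain transcripts 7 had positive folds, with a negative median (-0.0094) and a positive mean (0.022), and 0.27 (SE 0.14) for cytochrome c oxidase subunit VIc (Fcc05715).

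Among lists standing for tissues and body functions, 0 transcripts passed over all transcripts tested at EC10. Lipid metabolism had 12 of 17 positive folds, with 0.75 (SE 0.29) for a delta5 fatty acid desaturase match (Fcc01007). The carbohydrate hydrolases had 5 of 10 positive folds, and 1 of them, the maltase-glucoamylase match, passed when adjusted over the list alone. Digestive proteases had 6 of 13 positive folds, with a median of -0.031 and a mean of 0.034, cuticle and moulting 6 of 7, muscle 6 of 9, neuronal 7 of 8 and immune 4 of 6. The protease list also holds a match to an inter-alpha-trypsin inhibitor (Fcc01478), which is not a protease. An endochitinase match (Fcc02522) had a log2 fold of 0.94 (SE 0.40), troponin C (Fcc04074), the calcium sensor of muscle, 0.39 (SE 0.16), a neurotrophic tyrosine kinase receptor match (Fcc05220) -0.35 (SE 0.20) and a peptidoglycan deacetylase match (Fcc04902) 0.49 (SE 0.25). The vitellogenin match (Fcc05618), a yolk protein precursor, had 0.26 (SE 0.31), and the beta2 tubulin match (Fcc05988) -0.16 (SE 0.36), which turned positive when array C-2/EC10-1 or EC10-2/AC-4 was left out. The beta-lactam list had 3 of 8 positive folds, with -0.23 (SE 0.13) for a match to the first enzyme of penicillin synthesis (Fcc00590), well above background in 1 of 4 EC10 and 1 of 3 acetone control samples. Cell cycle and histones had 4 of 6, with 0.10 (SE 0.16) for a histone acetyltransferase match (Fcc04605). No tested member of that list matches a histone itself. The list of bacterial and yeast matches had 2 of 8, with -0.20 (SE 0.10) for Fcc00499, well above background in 1 of 4 and 1 of 3 samples. None of the 19 lists large enough to test passed camera at EC10 (lowest adjusted p = 0.13, 3 lists at an unadjusted p under 0.05). Left out in turn, 3 arrays changed this at the preset correlation, the only one run with an array left out. There 6 lists passed without C-2/EC10-1, and 1 list, ribosomal proteins, passed without AC-2/C-3 and again without EC10-2/AC-4. With all arrays, the estimated correlation of the ribosomal list was 0.51. Without AC-3/EC50-1 the ribosomal list turned downward (adjusted p = 0.70), and camera's direction turned for 12 of the 19 lists with at least 1 array left out.

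The second comparison set the higher concentration against the acetone control. Among transcripts with an informative match, the maltase-glucoamylase match again had the smallest p, and neither it nor the other 4 given here passed the test. The maltase-glucoamylase match (Fcc00529) stood at 12.46 ± 0.62 log2 intensity (SD, n = 4) in EC50 and 11.82 ± 0.36 (SD, n = 3) in the acetone control, with a log2 fold of 1.09 (SE 0.22). The CYP6N4v1 match (Fcc01651) stood at 7.08 ± 0.28 (SD, n = 4) against 6.29 ± 0.34 (SD, n = 3), with a log2 fold of 0.55 (SE 0.12). It was well above background in 4 of 4 EC50 samples and 1 of 3 acetone control samples. Another P450 match (Fcc00015) had the opposite sign, -0.65 (SE 0.15), with 6.86 ± 0.35 (SD, n = 4) in EC50 and 7.48 ± 0.82 (SD, n = 3) in the acetone control. A match to a fumarylacetoacetate hydrolase domain protein (Fcc02209), named for an enzyme of tyrosine breakdown, had a log2 fold of 0.89 (SE 0.22), and the purine nucleoside phosphorylase match (Fcc04684) 0.78 (SE 0.20).

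**Figure D1:**
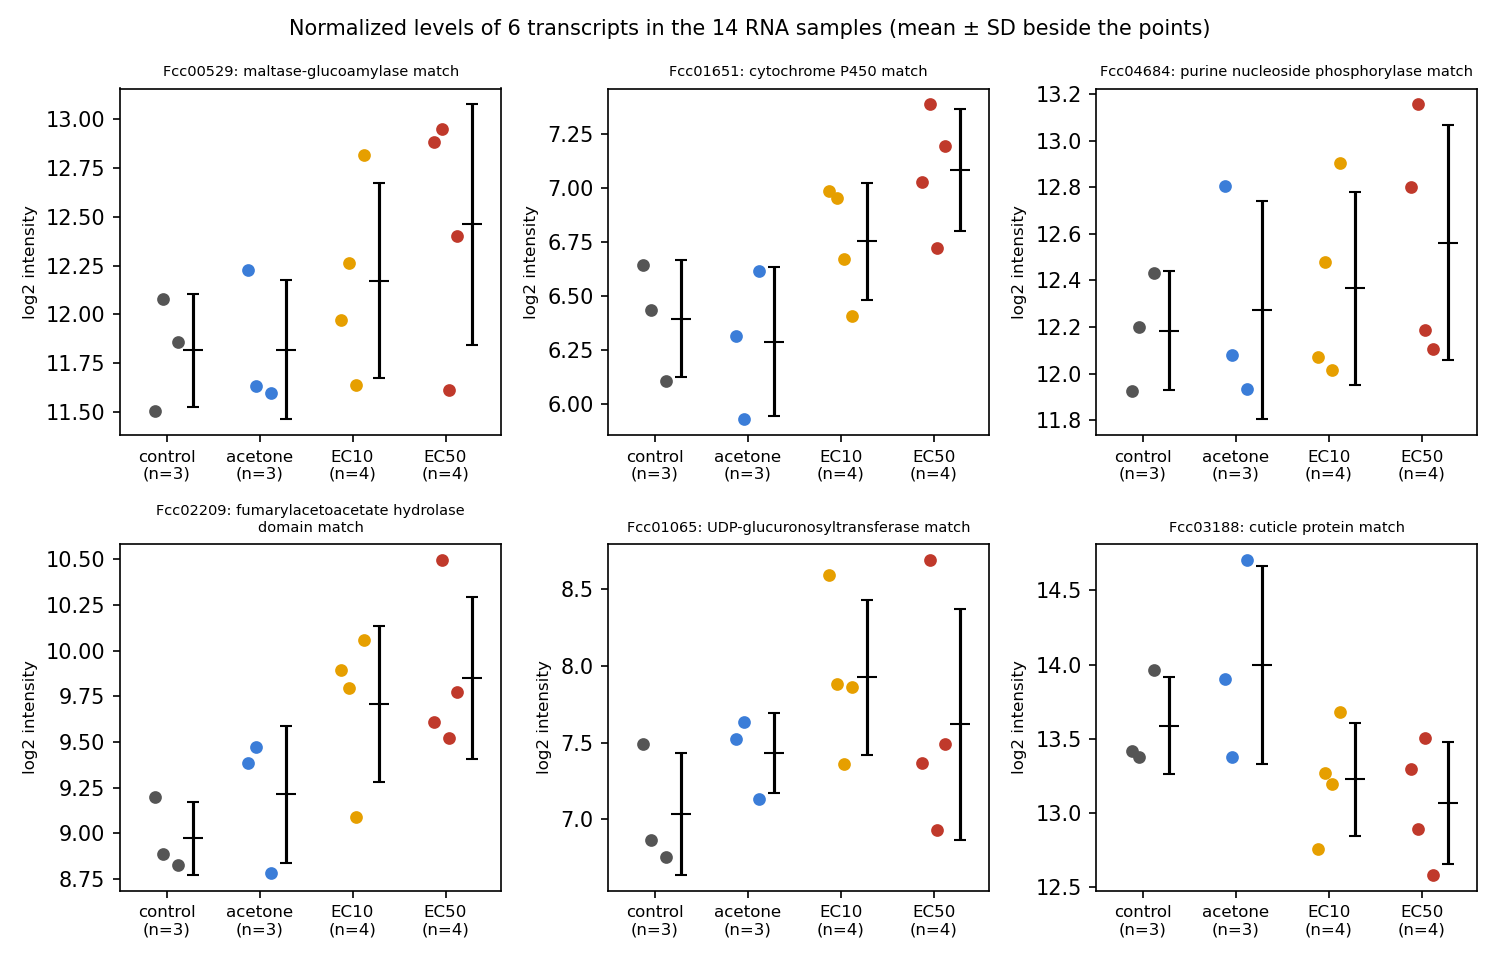
Normalized log2 intensity (y axis) of 6 transcripts in each of the 14 RNA samples, by group (x axis); each point is 1 pool of animals and the bars beside the points are the mean ± SD (control and acetone control n = 3, EC10 and EC50 n = 4). The single pools of the groups overlap for most transcripts; the cytochrome P450 match averages 6.29 in the acetone control and 7.08 in EC50, and no transcript passed the test of the ratio fit.

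In EC50 against acetone control, limma called 0 of 4542 transcripts (lowest adjusted p = 0.992). At an unadjusted p under 0.05 there were 173, 103 with a positive and 70 with a negative fold, where 227.1 would arise by chance. The separate-channel fit also called 0, with 379 at that level, and with the slide as a block 0 were called and 155 reached it. Without array C-2/EC10-1 that number was 331, and with array weights it was 938, with 0 called. On simulated data with independent transcripts, the same fit called 13.7% of transcripts changed by 0.5 log2 units in EC50 against acetone control. It called 59.7% of those changed by 1, 96.7% of those changed by 2 and 99.3% of those changed by 3. Each run held 50 changed transcripts of each size, and its noise had the spread after eBayes, not the raw residual spread. These shares can therefore not be taken as those of the measured data.

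Of 14 P450 transcripts at EC50, 10 had positive and 4 negative folds, and 0 passed over all transcripts. Adjusted over the list alone 2 passed, Fcc01651 and Fcc00015, with opposite signs. Glutathione S-transferases had 11 of 17 positive folds, with 0.48 (SE 0.25) for a match to the frog protein Gstm2prov (Fcc05335), and 0 passed in either adjustment. The other conjugating and detoxifying enzymes had 6 of 9 positive folds, with 0.32 (SE 0.18) for a carboxylesterase match (Fcc04282), and a camera adjusted p = 0.13. ABC transporters had 4 of 7, with -0.29 (SE 0.18) for Fcc04408. Their median was 0.18 and their mean 0.02, while camera gave the direction as down.

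Most proteasome and ubiquitin folds were negative at EC50, and the list did not pass the test. Of 19 transcripts 15 had negative folds, with a median of -0.12 and -0.29 (SE 0.14) for a proteasome subunit match (Fcc00083). The camera adjusted p was 0.071, and adjusted p = 0.70 with an estimated correlation. In the muscle list 8 of 9 folds were positive, with a median of 0.22, 0.41 (SE 0.16) for troponin C (Fcc04074), an adjusted p = 0.071, and adjusted p = 0.70 with an estimated correlation. Antioxidant transcripts had 7 of 12 positive folds, with -0.17 (SE 0.09) for a ferritin match (Fcc04961), and heat shock and chaperone transcripts 5 of 10, with 0.27 (SE 0.23) for Fcc01918, a median below 0 and a mean of 0.040. Ribosomal proteins had 20 of 36, with 0.54 (SE 0.20) for L38 (Fcc01536). Their median was 0.04 and their mean -0.003. Respiratory chain transcripts had 5 of 15, with -0.63 (SE 0.24) for a vacuolar ATP synthase subunit match (Fcc03280), a proton pump of acidic compartments rather than of mitochondria.

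Among tissue and body function lists at EC50, lipid metabolism had 7 of 17 positive folds, with 0.51 (SE 0.29) for the desaturase match (Fcc01007), and digestive proteases 5 of 13, with -0.26 (SE 0.10) for a cathepsin L match (Fcc01653). The carbohydrate hydrolases had 7 of 10, and 1, the maltase-glucoamylase match, passed when adjusted over the list alone. Cuticle and moulting had 4 of 7, with -0.63 (SE 0.21) for a cuticle protein match (Fcc03188). Neuronal transcripts had 4 of 8, with a median just above 0, a mean of -0.029 and -0.28 (SE 0.20) for Fcc05220, immune transcripts 5 of 6, with -0.48 (SE 0.28) for a lectin match (Fcc02832), and cell cycle and histones 4 of 6, with 0.34 (SE 0.23) for Fcc04847. Beta-lactam transcripts had 4 of 8, with 0.74 (SE 0.28) for an isopenicillin N synthetase match (Fcc01821), which closes the penicillin ring. That transcript spread widely in EC50, at 9.13 ± 1.31 (SD, n = 4), and its list had a median below 0 and a mean of 0.26. Vitellogenin (Fcc05618) had 0.26 (SE 0.31), tubulin (Fcc05988) -0.47 (SE 0.36) and the yeast match Fcc03836 -0.35 (SE 0.16), where 1 of the 8 folds of its list was positive. None of the 19 lists passed camera at EC50 (4 lists at an unadjusted p under 0.05). With an array left out, only the preset correlation was run. Without array AC-3/EC50-1, the only one on its slide, 2 lists passed, proteasome and ubiquitin and ribosomal proteins, both downward. That fit also gives the value within the other slide, but lacks the only array that set EC50 directly against the acetone control. With all arrays, the ribosomal list had an estimated correlation of 0.51. Without EC10-3/EC50-2 the muscle list passed upward, and without EC50-3/C-4 the list of bacterial and yeast matches passed downward. With at least 1 array left out, camera's direction turned for 13 of the 19 lists.

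**Figure D2:**
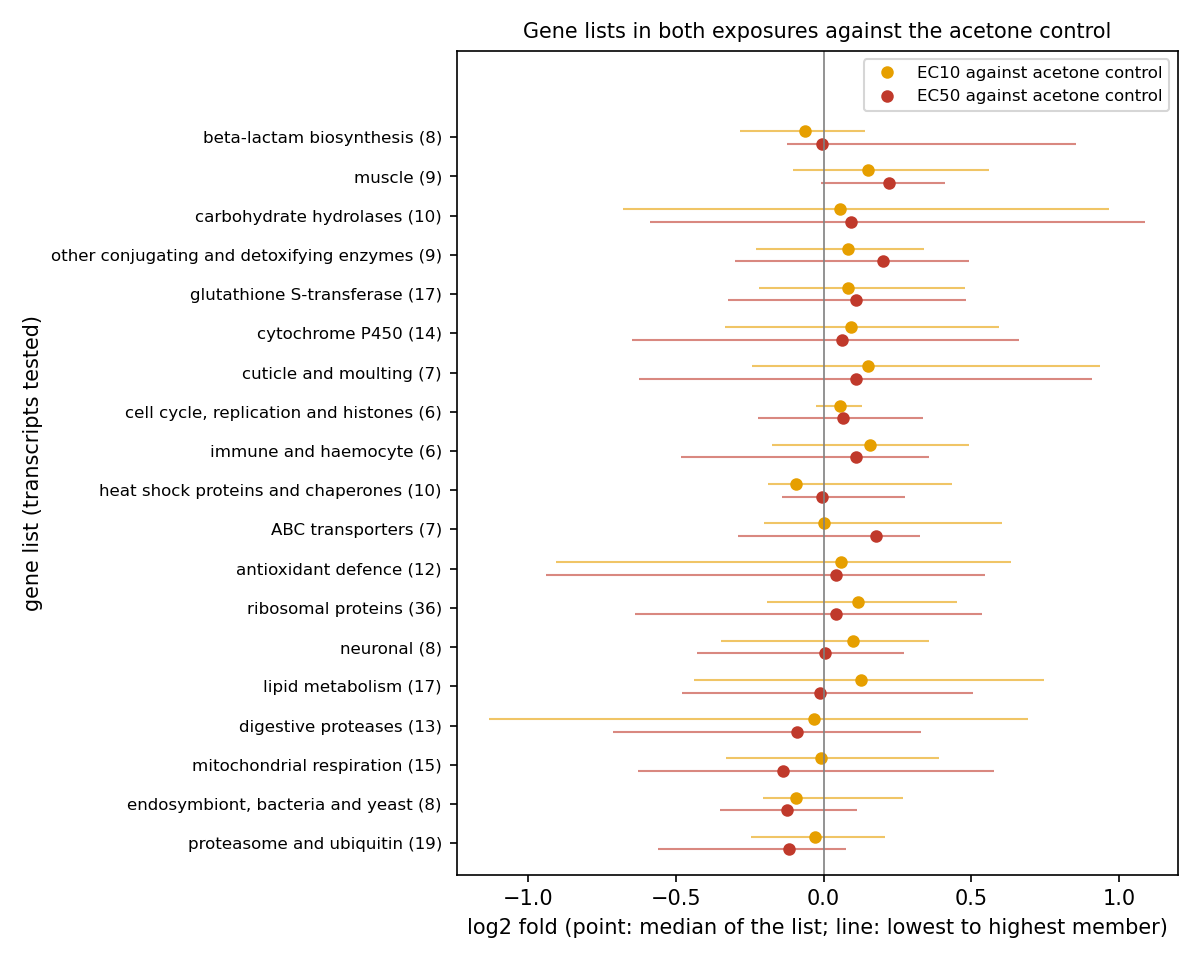
Log2 folds (x axis) of the 19 gene lists with at least 5 transcripts tested (y axis, number of transcripts in brackets) in EC10 and EC50 against acetone control; points are list medians and lines run from the lowest to the highest member. The medians lie near 0, the highest being 0.22 for muscle at EC50, and no list passed the camera test.

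The folds of both exposures against the acetone control were set side by side, which asks whether the concentrations moved the same transcripts. Across transcripts, which are not independent replicates, they correlated with r = 0.71 and a Spearman rho of 0.58, and 70.1% had the same sign. Both exposures share the acetone control samples. Simulated unchanged groups in the same design gave a mean r of 0.64, from 0.56 to 0.70 in 200 simulations, and 72.3% with the same sign. The observed covariance of 0.060 lay below the simulated one of 0.070, a difference of -0.011. With EC10 against acetone control and EC50 against control, r was 0.30, where the simulations gave 0.07 on average and 0.22 at most, and the covariance exceeded the simulated one by 0.027. With EC10 against control and EC50 against acetone control, r was 0.47, where the simulations gave 0.07 on average and 0.20 at most, and the covariance exceeded the simulated one by 0.044. These last pairs of comparisons share no control group. The simulated transcripts are independent, unlike measured ones, which can make the simulated range too narrow. For the pair sharing the acetone control, relabelled samples gave up to 0.97, where the simulations gave at most 0.70. No relabelling was run for the pairs without a shared control, so chance is not excluded for them. The acetone control could not be divided into parts of at least 2 samples for the comparisons that share it. Since 0 transcripts were called in each exposure, there was no overlap of calls.

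Between the concentrations, EC50 against EC10, the smallest p-values among transcripts with an informative match belonged to the P450 match Fcc00015, with a log2 fold of -0.52 (SE 0.13), and to a Kunitz-type protease inhibitor match (Fcc01155), with 0.23 (SE 0.06). A match to an enzyme of sterol synthesis (Fcc03247) had 0.34 (SE 0.09), a glycine receptor match (Fcc01574) 0.48 (SE 0.15) and Fcc00585 0.31 (SE 0.09). Separate channels gave 0.11 for Fcc00585, whose levels ran from 6.36 to 7.55 in EC10 and from 6.47 to 7.12 in EC50. The inhibitor and the receptor were well above background in 4 of 4 EC50 samples and in 2 of 4 and 3 of 4 EC10 samples. Limma called 0 of 4542 transcripts (lowest adjusted p = 0.987), with 123 at an unadjusted p under 0.05. The separate-channel fit called 0, with 118 at that level, and the fit with the slide as a block called 0, with 200. The fit with array weights called 802, and the number at that level was 827 without array C-2/EC10-1, 204 without AC-3/EC50-1 and 56 without EC10-3/EC50-2.

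The effect of the solvent was read from acetone control against control. The 5 transcripts with the smallest p-values among those with an informative match all had positive folds, and none passed the test. A match to the cap-binding translation factor eIF4E (Fcc06205) was at 11.76 ± 0.47 log2 intensity (SD, n = 3) in the acetone control and 11.29 ± 0.15 (SD, n = 3) in control, with a log2 fold of 0.80 (SE 0.16). Adenylate kinase (Fcc03119), which balances adenine nucleotides, had 1.04 (SE 0.21), a nin one binding protein match (Fcc00324) 0.79 (SE 0.18), a malate synthase match (Fcc00992) 0.81 (SE 0.19) and an N-acetylglucosamine kinase match (Fcc01943) 0.81 (SE 0.19). Limma called 0 of 4542 (lowest adjusted p = 0.802), with 264 at an unadjusted p under 0.05, and 0 with the slide as a block, with 152 at that level. The separate-channel fit called 3 transcripts, all higher in the acetone control, and the fit without array C-2/EC10-1 called 4, all higher, with 619 at that level. It was 153 without AC-3/EC50-1, 147 without EC10-2/AC-4 and 133 without EC10-3/EC50-2 and again without EC50-3/C-4, and with array weights it was 1128, with 0 called.

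Against untreated control, the transcript with the smallest p in EC10 among those with an informative match, a match to the UDP-glucuronosyltransferase UGT1A10 (Fcc01065), which attaches sugar acids to small molecules, had a log2 fold of 1.41 (SE 0.25), at 7.92 ± 0.51 (SD, n = 4) and 7.04 ± 0.40 (SD, n = 3). It did not pass the test. A match to a GABA-gated chloride channel (Fcc04565) had 0.60 (SE 0.12), well above background in 2 of 3 control samples, Fcc01943 had 0.92 (SE 0.18) and a calcineurin B2 match (Fcc05924), the regulatory subunit of a calcium-dependent phosphatase, 0.74 (SE 0.15). The CYP6N4v1 match (Fcc01651) was not well above background in any control sample. With dim samples set to their channel's lowest signal well above background, where that was higher, its mean was at least 1.14-fold higher in EC10. Such a bound on the mean comes from separate channels, stays open to dye bias and leaves out the spread between samples. Control 2 (6.65) lay above EC10 replicate 2 (6.41), and the transcript did not pass the test. Limma called 0 of 4542 (lowest adjusted p = 0.544), with 368 at an unadjusted p under 0.05. With the slide as a block 0 were called, with 322 at that level, and the separate-channel fit called 0, with 615. Without array C-2/EC10-1, the fit called 34, of which 33 were higher and 1 lower in EC10, with 900 at that level. That array was the only direct hybridisation of control with EC10, so without it these folds come through other groups. The level held 203 without EC10-3/EC50-2 and 194 without EC50-3/C-4, and the fit with array weights called 1886.

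In the ratio fit of all arrays without weights, EC50 against control held the most transcripts at an unadjusted p under 0.05, 683. Of these, 346 had positive and 337 negative folds. EC10 against control held more without array C-2/EC10-1 (900 against 814) and with array weights (2380 against 1937). The fumarylacetoacetate hydrolase domain match (Fcc02209) was at 9.85 ± 0.44 (SD, n = 4) in EC50 and 8.97 ± 0.20 (SD, n = 3) in control, with a log2 fold of 1.30 (SE 0.22). The calcineurin B2 match (Fcc05924) had 0.87 (SE 0.15) and the GABA-gated chloride channel match (Fcc04565) 0.75 (SE 0.12). The mean of the CYP6N4v1 match (Fcc01651) was at least 1.43-fold higher in EC50 by the same kind of bound. A match to diptericin, an antibacterial peptide of flies (Fcc02054), was well above background in 2 of 3 control samples and in 0 of 4 EC50 samples. Its mean was 1.36-fold lower with the remaining control at its measured signal, which is no strict bound. Both values leave out the spread between samples, and neither transcript passed the ratio fit (limma adjusted p = 0.18 for each). Limma called 0 of 4542 (lowest adjusted p = 0.114), and 0 with the slide as a block, with 644 at an unadjusted p under 0.05. The separate-channel fit called 89, 46 higher and 43 lower in EC50, among them Fcc02209, Fcc05924 and Fcc02054, and the same fit with the replicate number as a block called 0. The fit without a dye term called 2, both lower, and that without array C-2/EC10-1 called 3, all higher. The fit with array weights called 1160, and the 683 became 374 without EC10-3/EC50-2 and 280 without EC50-3/C-4.

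Over all 4 groups together, the moderated F test called 0 of 4542 transcripts (lowest adjusted p = 0.741), with 277 at an unadjusted p under 0.05 where 227.1 would arise by chance. With the slide as a block 0 were called, with 242 at that level, while the separate-channel fit called 1 and the fit without array C-2/EC10-1 called 2, with 701 at that level. It was 145 without EC10-3/EC50-2 and 138 without EC50-3/C-4, and the fit with array weights called 2040. The mean residual variance of the ratios with the group and dye terms was 0.232, and their mean variance around each transcript's own mean over the arrays was 0.229.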

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

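Among 100 groups of 4 samples over the named transcripts, 9 had a sample far from the other 3 by Dixon's criterion, where chance gives about 5. In EC10, the ABC transporter match Fcc05098 stood at 11.51 log2 intensity in replicate 1 against 9.85 to 9.93 in the others. The yeast match Fcc00499 was at 6.62 in replicate 2 against 6.17 to 6.24, and the malate synthase match Fcc00992 at 10.46 in replicate 4 against 10.84 to 10.91. In EC50, ribosomal protein L38 (Fcc01536) was at 15.91 in replicate 3 against 15.42 to 15.47. The tyrosine kinase receptor match Fcc05220 was at 11.54 in the same replicate against 11.85 to 11.90. The glutathione S-transferase match Fcc05335 was at 9.22 in replicate 1 against 8.63 to 8.68, and calcineurin B2 (Fcc05924) at 11.03 in that replicate against 11.63 to 11.70. In replicate 4, the penicillin synthesis match Fcc00590 was at 6.62 against 6.18 to 6.23, and diptericin (Fcc02054), not well above background in EC50, at 6.28 against 6.20 to 6.21. No effect was shown to differ between the concentrations, and no signal outside the main measurement was read.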

How the results depend on the processing

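All alternatives reported here were chosen before the data were examined. The counts of 0 called transcripts stayed at 0 without background correction, with the scanner software's processed signals, with scaling between arrays, with either filter on dim transcripts, with the deposited table and with the slide as a block. Leaving out the dye term gave 2 calls in EC50 against control. Separate channels gave 89 in EC50 against control, 3 in acetone control against control and 1 over the 4 groups, and the same fit with the replicate block gave 1 in acetone control against control and 0 in the other comparisons, so the replicate block ended the 89 calls. Same-numbered samples of different groups deviated from their group means with a median correlation of -0.07 (-0.58 to 0.24 over 18 pairs). Differently numbered ones had 0.018 (-0.52 to 0.53 over 48 pairs), and 2 of 14 samples correlated best with their own number. So few samples cannot show whether the numbers mark a batch. Array weights, from 0.114 for C-2/EC10-1 to 7.84 for EC50-4/EC10-4, gave 802 calls in EC50 against EC10, 1886 in EC10 against control, 1160 in EC50 against control and 2040 over the 4 groups. The estimation of the weights stopped before it converged. Other splits of the control and EC10 samples gave up to 761 calls with weights, against 1886 for the real split, the only 1 of 35 with as many, but this comparison has the most calls of the 6 with weights, with no allowance for that choice, so chance is not excluded. Leaving out each array gave 0 to 4 calls in acetone control against control, 0 to 34 in EC10 against control, 0 to 3 in EC50 against control, 0 to 2 over the 4 groups and 0 in the others, all from C-2/EC10-1. With an array left out and the preset correlation, the lists passing camera ranged from 0 to 6 for EC10 and 0 to 2 for EC50 against acetone control. They were 0 without the dye term, with transcripts well above background in all channels, with separate channels and with an estimated correlation. Those were the other alternatives run for lists. The correlation of the folds ranged from 0.47 (without C-2/EC10-1) to 0.87 (without EC10-2/AC-4), and was 0.30 with EC50 against control in place of the acetone control. For the changes under other settings the cause was not tested. Of 68 named values 5 changed sign with an array left out: Fcc05988 (-0.35 to 0.29), Fcc04605 (-0.038 to 0.48) and Fcc00590 (-0.32 to 0.016) at EC10, and Fcc01918 (-0.014 to 0.55) and Fcc05618 (-0.094 to 0.51) at EC50. The alternatives run for all named values, without the dye term, with processed signals and with separate channels, changed no sign, and separate channels brought 3 values, Fcc02209, Fcc05924 and Fcc02054 in EC50 against control, past the threshold. The probe-level alternative is the same test, since each transcript has 1 probe. Signal near background limits the named transcripts that only some samples measured above background.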

Other observations

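The list tests for control and between the concentrations, the pooled test of acetone, and the tests of the block of transcripts, of its slides and of array signals were chosen after the data were seen, and so was the final reading of the tests for exchanged dyes and weak signal. Against untreated control, 1 enzyme list passed camera at both concentrations with the preset correlation and at neither with an estimated one. All 9 of the other conjugating and detoxifying enzymes had positive folds in EC10, with a median of 0.52 and a camera adjusted p = 0.0044, and 8 of 9 in EC50, with a median of 0.42 and an adjusted p = 0.030. With an estimated correlation these became adjusted p = 0.60 and adjusted p = 0.87. The estimate was -0.0056, below the preset 0.01, so the fewer degrees of freedom, not correlation between members, raised these values. The carbonyl reductase match Fcc01157 had 0.77 in EC10. In the acetone control itself 8 of 9 were positive, with a median of 0.30 and an adjusted p = 0.23. Of 35 splits of the control and EC10 samples, 1 gave as small a p for this list, the real one, with 3.63 as its negative log10 and 3.43 in the next split. This list had the smallest p of 19 and was picked for it, with no allowance for the others, so chance is not excluded. Of its 9 transcripts 1 passed when adjusted over the list alone and 0 over all transcripts. The UDP-glucuronosyltransferase match Fcc01065 was not one of the 9, since the keywords did not find it. The highest fold among the 9 in EC10 against control was 0.77. Glutathione S-transferases had 13 of 17 positive folds in EC10 against control, a median of 0.19 and an adjusted p = 0.047 (adjusted p = 0.87 with an estimated correlation), but 2 of 35 splits gave as small a p (negative log10 of 2.13, against 2.77 in another split), so chance is not excluded. In EC50 against control 12 of 17 were positive and the list did not pass (adjusted p = 0.32), and the cytochrome P450 list passed at neither concentration (adjusted p = 0.25 in EC10 and adjusted p = 0.49 in EC50). Ribosomal proteins had 27 of 36 positive folds in EC10 against control, a median of 0.16 and an adjusted p = 0.045 (adjusted p = 0.87 with an estimated correlation), and 22 of 36 in EC50 against control, a median of 0.10 and an adjusted p = 0.66. The estimated correlations of the glutathione S-transferase and ribosomal lists, 0.23 and 0.51, lay above the preset 0.01, which also raised their p-values. Between the concentrations, 14 of 17 lipid metabolism transcripts had negative folds in EC50 against EC10 and 6 of 8 beta-lactam transcripts positive ones, and neither list passed (adjusted p = 0.11 for both, and adjusted p = 0.87 with an estimated correlation).

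Other groupings of the same samples often gave as many transcripts at an unadjusted p under 0.05 as the real one. This held for 21 of 35 splits for EC10 against acetone control (139 against at most 946 elsewhere), 17 of 35 for EC50 against acetone control (173, 791), 18 of 34 that could be fitted for EC50 against EC10 (123, 1219), 8 of 35 for EC10 against control (368, 643), 2 of 35 for EC50 against control (683, 811) and 40 of 100 over the 4 groups (277, 696), so chance is not excluded for any of them. For acetone control against control, 10 splits are too few for a share under 0.05, with 264 in the real split and 564 as the highest other. For EC50 against EC10, 3 of the 34 splits called transcripts, at most 96, where the real one called 0. Splits also called transcripts in EC50 against acetone control (4 of 35, at most 5) and EC10 against control (1 of 35, 15). EC10 against acetone control had 1 of 35 with 1 call, acetone control against control 1 of 10 with 1, and EC50 against control 0. What lies behind these calls was not tested. For lists, 29 and 26 of 35 splits gave as many as the 3 and 4 at an unadjusted p under 0.05 in EC10 and EC50 against acetone control, with at most 8 in another split. Of 100 relabellings, 36 gave a correlation of the EC10 and EC50 folds as high as 0.71, at most 0.97 in another.

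The first pattern was a block of 10 transcripts, those that correlated above 0.9 with the most variable one (Fcc00575), 9 of them without a listed match, whose identifiers were chosen after their values were seen. Their mean log2 level was 6.43 in EC50 replicate 3, 6.91 in EC50 replicate 1 and 7.52 in acetone control 4, and at least 9.09 in the other 11 pools, and Fcc03966 ran from 7.53 in EC50 replicate 3 to 14.05 in EC50 replicate 4. The isothiocyanate as the whole cause is excluded, because the lowest unexposed pool minus the highest EC50 pool gave -3.23. Failed labelling across all probes of these channels is excluded, because 5 of the other channels had fewer probes well above background than all 3. The slide is excluded too, because the 3 pools lay on 2 slides. A fault limited to 1 array or to some probes was not tested. Acetone control 4 and EC10 replicate 2, which shared an array, had the highest shares of probes well above background (98.1% and 94.1%). No biological explanation besides exposure was tested.

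The second pattern was that EC50 against control held 683 transcripts at an unadjusted p under 0.05, and EC50 against acetone control 173. Acetone in the soil may be the cause, since all groups but control had it. Over the 683, the acetone control carried a median share of 0.593 of the difference, but 55% of 100 relabellings gave as high a share, so this cannot be told apart from the control samples they have in common. The folds of the acetone control and of EC50 against control correlated at 0.69 across transcripts, above simulated unchanged groups with the same control (0.54 on average, 0.62 at most), and their covariance exceeded the simulated one by 0.034, but the simulated transcripts are independent, unlike those relabelled. Pooling the other 11 samples against control gave 0 calls and 648 at an unadjusted p under 0.05, and 7 of 100 choices of 3 samples as control gave as many (at most 844), so chance is not excluded either.

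The third pattern was that calls appeared when array C-2/EC10-1 was left out, 34 in EC10 against control. No other array set control directly against EC10, so the folds behind these 34 came through other groups. Weak Cy5 signal is excluded as the cause, since 4 arrays had a lower median (1537 intensity units here), while weak Cy3 signal stays open, with 1 array lower (199.6 against 205.5), AC-3/EC50-1, without which 0 transcripts were called. The array's ratios, less the dye term fitted to the other 6 arrays, correlated at -0.42 across transcripts with the group differences predicted from those 6. This met the bound of -0.3 written beforehand for dyes entered the wrong way round. Errors of the dye term enter both sides of this correlation, and its size without any effect was not computed, so the bound alone cannot decide. After this value was seen, that bound was no longer taken as sufficient, because EC10-2/AC-4 (-0.36) and EC50-4/EC10-4 (-0.33) also met it, turning the array gave 0 calls in EC10 and EC50 against control, and it left the residual variance at 0.228 (0.232 unturned), where turning EC50-4/EC10-4 gave 0.192. Exchanged dyes and differences between single jars therefore cannot be told apart.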
